A study of Arabidopsis thaliana with 15 samples.

How the data were processed

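RNA of 15 samples, 3 at each of 0, 12, 24, 36 and 48 h, was measured on 1-colour Affymetrix arrays. Per the labels' protocols, the authors prepared total RNA from the leaf disks, made biotin-labelled cRNA and hybridised 1 array per sample. The deposited values are intensities on a linear scale, computed with GCOS and MAS5 per the submitters' processing notes; their versions are not given in the sources used here. The values themselves showed that each array had been scaled to a common mean trimmed by 2%. That scaling sets the mean of each array alike, so a change shared by most transcripts would be hidden, and it left the median signals between 121.8 and 169.9. No detection calls were used, so folds that rest on signals below about 30.7 are uncertain. No arrays held identical values.

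From these intensities log2 values were taken with no offset and no further normalization. The 64 Affymetrix control probe sets were left out. A probe set was kept where the highest of its 5 group means reached the percentile 30 of all group means, a signal of 30.7, which kept 17829 of 22746. The test was limma 3.58.1 in R 4.3.3 on 5 group means over all 15 arrays, with 10 residual degrees of freedom, a two-sided moderated test per contrast, and Benjamini-Hochberg adjustment over all probe sets kept. A probe set was called at an adjusted p under 0.05. The F test covered the 4 contrasts against 0 h. The fit was tested on simulated data with the spread of the real arrays. Over 17829 probe sets, the simulation of 48 h against 0 h recovered 20.9% of planted 2-fold, 65.7% of 4-fold and 83.3% of 8-fold changes, and that of 36 h against 24 h recovered 20.9%, 53.7% and 75.8%. Probe sets without a planted change made up 6.6% (8) and 4.8% (5) of the calls, against a nominal 5%. Each simulation planted only 67, 67 and 66 changes of these sizes, whereas the real comparison of 48 h with 0 h called 10165 probe sets. With few planted changes the adjustment is stricter, so these rates do not give the power of that comparison. The simulated values were also drawn independently, without any correlation between arrays of the same replicate number.

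Genes were named through the platform annotation table, in which 13513 probe sets had 1 gene, 503 had several and 8730 were not listed. Of those with 1 gene, 13436 matched a locus of the TAIR10.1 gene table, which served for names only. Among kept probe sets 9861 loci were named, 103 of them by more than 1 probe set, and 1 to 2 loci had probe sets called in opposite directions in the contrasts against 0 h. In list tests a gene was represented by its probe set with the highest mean. Unlisted probe sets are unnamed here, not without a gene.

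The main design, the rule for named genes, 21 gene lists and most alternatives were fixed before the data were examined. The rule took, against 0 h, the 6 highest and 6 lowest changes among called probe sets with 1 gene whose replicates did not overlap between the groups, and for steps between later times the 4 highest and 4 lowest. From each list it took the 2 called members with the largest change, or the largest change if none was called, and for steps the called members with the largest change. It also named 13 genes of xylem and phloem whatever their values, but 0 of them were paired with a probe set in the annotation table, and they were not analysed here. Of 378 members of the fixed lists, 52 were paired with a probe set, and 5 lists had no measured gene. Another 25 lists were written from the annotation table after the data were in hand and before values of genes were seen; those given most room were chosen after the list tests were seen. Lists with at least 5 measured genes were tested with limma's camera at a preset correlation of 0.01, adjusted over 21 tests of fixed lists and 175 of added lists. Of 71 called tests, 0 held with a correlation estimated from the data. A second planned test, limma's fry, does not compare a list with other probe sets, and its verdicts differed from camera's in both directions. For procambium and cambium at 24 h against 0 h fry gave adjusted p = 5.94e-04, where camera gave 0.0587. For photosynthesis at 36 h against 24 h fry gave adjusted p = 0.0738, where camera gave 2.77e-06. Only camera results are given below.

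The labels number the replicates, except for the third array of 36 h, which is called 3 here by order alone. Whether the numbers pair the samples was checked by correlating the arrays' deviations from their group means. Pairs with the same number correlated at 0.014 to 0.496, and pairs with different numbers at -0.471 to 0.051. Between neighbouring times the same-number correlations were 0.381, 0.147 and 0.449 for 12 and 24 h, 0.496 and 0.292 for 24 and 36 h (0.550 with the unnumbered array), and 0.476 and 0.324 for 36 and 48 h (0.463 with it). These steps are therefore also given with the replicate number as a block; against 0 h some pairs lay below 0.1. The pairing comes from the data and the shared numbers, not from a statement in the labels.

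Alternatives were quantile normalization, median centring, an offset at the percentile 10 of signals (4.2), no filter, a stricter filter at the percentile 50, a filter on the mean, an intensity trend with robust estimation, array weights, a fit of only the 2 times compared, the replicate block, leaving out probe sets that can match several genes, the mean of a gene's probe sets, and leaving out each array in turn. Leaving out all arrays of number 3, the stricter filter together with the block, and comparing lists with named genes only were added after seeing the data.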

Results

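The series followed leaf disks of the Arabidopsis thaliana ecotype Col-0 during an induced differentiation of xylem cells, the water-conducting cells of the vascular tissue. Disks of 1 mm diameter were cut from rosette leaves of 25-day-old seedlings. They were cultured in a medium with 1.25 mg/L of the synthetic auxin 2,4-D and 0.25 mg/L of the cytokinin kinetin. The medium also held 10 µM of bikinin, an inhibitor of the GSK3 kinases that restrain brassinosteroid signalling. Disks were sampled at 0, 12, 24, 36 and 48 h, with 3 arrays at each time and 15 in all. No disks cultured without these compounds were among the samples. In every comparison of times, effects of the compounds therefore cannot be told apart from those of cutting, culture or passing time. Biotin-labelled cRNA made from total RNA was hybridised to a 1-colour Affymetrix array. Of the 22746 probe sets that were not controls, 17829 passed the filter on dim signals. Among those kept, 9967 were paired with a single locus, and the genes named here come from these. A list's measured genes are its members among them. Of 378 members of the fixed lists, only 52 were paired with a probe set, among them 1 of 25 xylem regulators. The others could not be looked up here, which does not mean that the array lacked them. The titles number the replicates but do not say that they were separate cultures from each other, so the p-values measure only the spread between these samples, which may be technical. The number of arrays limits the precision. Folds against a signal below about 30.7, such as the 0 h signals of GSTU25, IRX15, PRX52 and GH9B8, are uncertain in size. That value is the filter's cutoff and not a limit of detection, so folds from signals above it can be uncertain too. Errors of log2 changes are standard errors from the limma fit over all 15 arrays, with n = 3 arrays per time, and adjusted p-values are Benjamini-Hochberg values of limma's moderated test.

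The arrays of 0 h stood apart from all later arrays. Across the probe sets kept, arrays of the same time correlated at r = 0.886 to 0.954, while a 0 h array and a later array correlated at 0.562 to 0.707. Arrays of different later times correlated at 0.715 to 0.960. The first principal component carried 51.1% of the variance and the second 18.2%. The median log2 signal of the arrays differed from that at 0 h by -0.05 at 12 h, 0.10 at 24 h, 0.19 at 36 h and 0.22 at 48 h, and changes of single genes stand relative to these shifts.

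**Figure D1:**
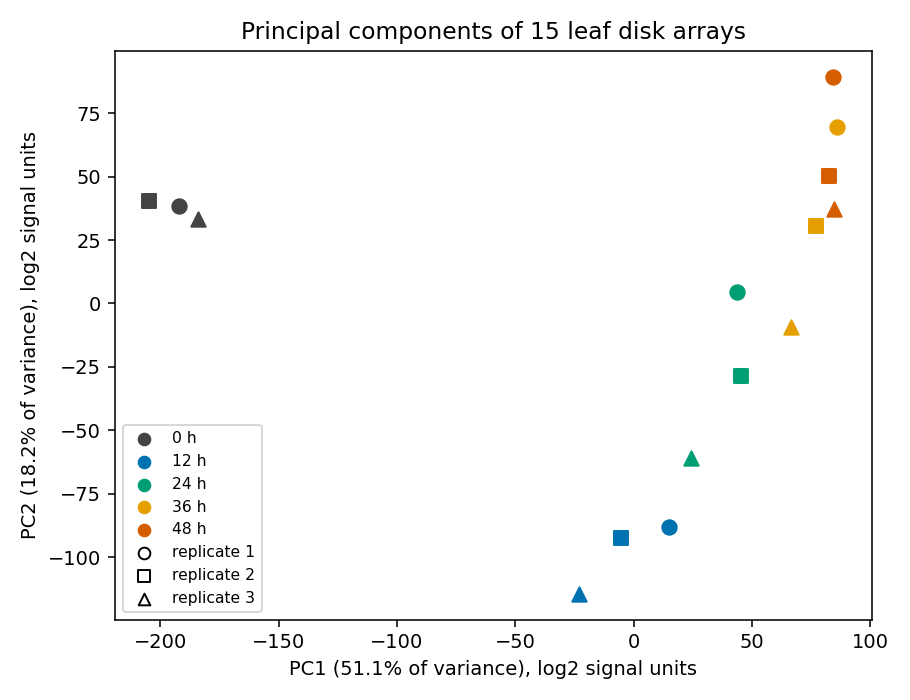
Principal components of the log2 signals of the 17829 probe sets kept, with 51.1% of the variance on the horizontal axis and 18.2% on the vertical axis, in log2 signal units. Each point is 1 array, coloured by time, with the marker giving the replicate number. The 3 arrays of 0 h lie apart from the 12 later arrays, which are spread along the second axis.

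The comparison of 12 h with 0 h asked what had changed at the first sampling after the disks entered the medium. Photosynthesis genes fell and auxin-responsive genes rose. All 10 measured members of the photosynthesis list fell, with a median log2 change of -4.19. The light-harvesting protein gene LHCB4.2 fell from a mean signal of 27820.0 to 302 (log2 change -6.53 ± 0.68, adjusted p = 1.11e-05), and PSAN, a subunit of photosystem I, changed by -5.83 ± 0.76. Of 8 measured auxin response genes, 5 rose and 1 fell. GH3.3, which encodes an enzyme that conjugates auxin to amino acids, rose 314-fold, from a signal of 67.0 to 21044 (log2 change 8.29 ± 0.56, adjusted p = 1.01e-06). IAA30 rose 41.9-fold, whereas WES1, another GH3 gene, had a log2 change of -1.91; it was the 1 member that fell and was picked out after its value was seen. The fall of WES1 was not called without 0 h replicate 1 (-1.80), 12 h replicate 2 (-1.19) or 0 h replicate 3 (-1.69). The cytokinin response regulator gene ARR15 rose 6.16-fold (adjusted p = 0.047), 1 of 2 measured members of that list, but the call was lost without any 1 of 5 of the 6 arrays, and the log2 change was 1.13 without 0 h replicate 1. CLE41 and CLE44, whose peptides maintain procambial cells, rose 2.8-fold and 4.69-fold, and they were the 2 called members among 5 measured procambium and cambium genes. In the phloem list, the sugar transporter gene SWEET11 fell and OPS rose (5.64-fold). None of the 3 measured secondary wall synthesis genes passed the test; IRX15-L had the largest change in size (-0.51 ± 0.60, adjusted p = 0.519), and its sign turned without 12 h replicate 2 (0.11).

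Other groups moved within the same 12 h. In the nucleolus and RNA polymerase I and III list, 10 of 11 measured genes rose, among them NRPC1 (26.2-fold) and YAO (9.95-fold). In the DNA replication list, 9 of 11 rose, including the polymerase subunit gene POLD3 (4.56-fold) and the histone H2B gene HTB4 (3.18-fold). In the mitosis list 3 of 17 rose, none adjusted over the list alone, the median change was 0.02, and the list was not called (camera adjusted p = 0.639). Among transcripts encoded in the plastid, 21 of 33 photosynthesis genes fell, with psbB at -2.32 ± 0.42 and rbcL at -1.89 ± 0.34 (camera adjusted p = 1.07e-05, adjusted p = 0.594 with an estimated correlation). The largest rises were those of the glutathione transferase gene GSTU25 (10.24 ± 0.68), AT4G12500 (9.41 ± 0.55), AT3G16330, the glycosyltransferase gene UGT73C1, AT4G12490 and GH3.3. Their 0 h signals lay below the filter's cutoff of 30.7 for GSTU25, AT4G12500, AT3G16330 and UGT73C1, so those folds rest on dim values; no detection calls were used here. The largest falls were those of AT1G62510 (-9.20 ± 0.94), AT4G15690, AT5G02160, AT1G70820, AT3G22210 and AT3G62950. The wound- and jasmonate-responsive gene ORA47 fell 62.9-fold from a signal of 5638, and JRG21 rose 74.8-fold, in a list of 9 with 1 rise and 2 falls that was not called (adjusted p = 0.630).

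In all, 8131 probe sets changed between 0 and 12 h, 4229 up and 3902 down, and 6717 of them by at least 2-fold. The camera test with a preset correlation of 0.01 gave adjusted p = 4.66e-08 for the photosynthesis list (adjusted p = 0.243 with an estimated correlation), 0.0188 for auxin response (adjusted p = 0.243 with an estimated correlation), 3.78e-05 for the nucleolus list (adjusted p = 0.508 with an estimated correlation) and 9.58e-04 for DNA replication (adjusted p = 0.490 with an estimated correlation). The nucleolus, DNA replication, mitosis and plastid lists were written after the annotation table was seen. Adjusted over the list alone, 10 photosynthesis genes fell, 5 auxin response genes rose and 1 fell, and 2 procambium and cambium genes rose.

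**Figure D2:**
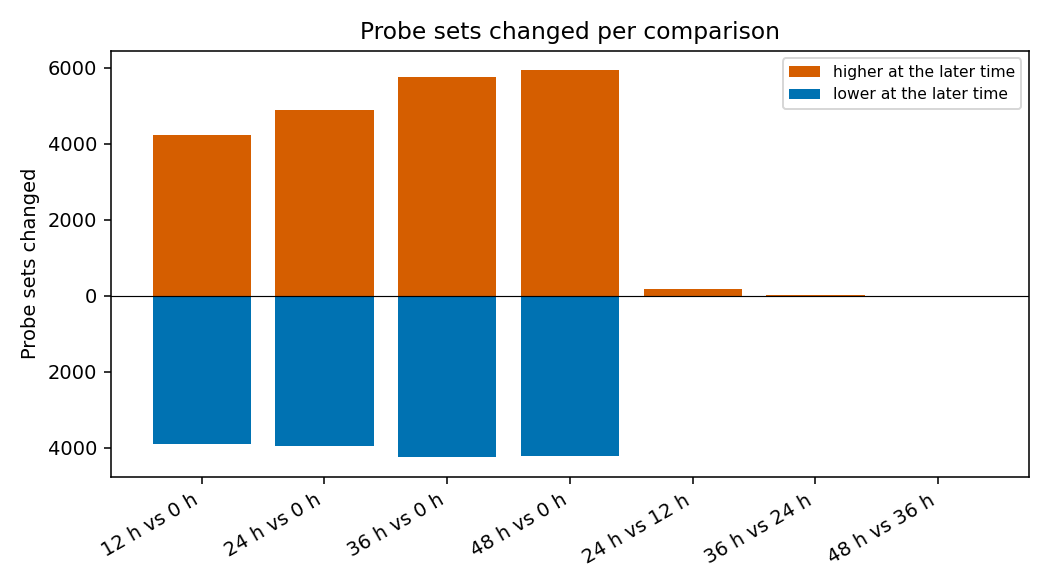
Number of probe sets that changed in each of 7 comparisons (limma, adjusted p under 0.05), with rises above the zero line and falls below it. Comparisons against 0 h gave between 8131 and 10165 probe sets, and comparisons of neighbouring later times gave 220, 20 and 0.

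At 24 h, the comparison with 0 h showed the photosynthesis list still low and cell division genes raised. All 10 measured photosynthesis genes were lower than at 0 h, with a median of -3.85, and the photorespiratory enzyme gene HPR stood at -5.03 ± 0.33. In the mitosis list 14 of 17 genes rose, including the Aurora kinase gene AUR2 (8.71-fold, adjusted p = 0.0014) and the ubiquitin-conjugating enzyme gene UBC20 (11.7-fold). All 11 DNA replication genes rose, with HTB2 at 8.31-fold and the MCM helicase subunit gene PRL at 8.18-fold. All 5 procambium and cambium genes rose, with CLE44 at 5.62-fold, although the list test missed its threshold (adjusted p = 0.0587). Of 8 auxin response genes, 5 rose and 1 fell. Of 3 secondary wall genes, IRX15, which acts in xylan synthesis, passed the test over all probe sets (4.7-fold), and adjusted over the list alone none did. Its signals of 6.1 and 28.5 both lay below 30.7, and the call was lost without 24 h replicate 2 (log2 change 1.44), 24 h replicate 3 (1.90), 0 h replicate 1 (2.04) or 0 h replicate 2 (1.96). The wall-loosening gene EXPA4 rose 28.2-fold, in an expansin list of 12 with 4 rises and 2 falls that was not called (camera adjusted p = 0.241). The endoglucanase gene GH9B8 rose 49.8-fold, in a list of 12 that also had 4 rises and 2 falls (adjusted p = 0.294). In the lignin list, the peroxidase gene PRX52 rose 57.2-fold, while CCR2 (-2.54 ± 0.95) and HCT (-1.13, named after its value was seen) fell. The fall of CCR2 was not called without 24 h replicate 1 (-1.25), 0 h replicate 1 (-2.55) or 0 h replicate 2 (-2.21). Of 2 measured xylem cell death genes, the vacuolar protease gene GAMMA-VPE fell (-2.17 ± 0.42) and scpl48 rose (1.90 ± 0.28). The highest changes were those of AT4G12500, GSTU25, AT4G12490, GH3.3, AT3G25640 and AT2G41800, and the lowest those of AT5G62360 (-8.72 ± 1.17), AT1G62510, AT4G21870, AT4G15690, AT4G27654 and AT3G62950. Adjusted over the list alone, the counts of the photosynthesis, auxin response, procambium and lignin lists were the same. Altogether 8843 probe sets changed, 4877 up and 3966 down, and 7411 by at least 2-fold. Camera gave adjusted p = 2.25e-07 for photosynthesis and 0.0175 for auxin response (both adjusted p = 0.243 with an estimated correlation), 0.0010 for mitosis (adjusted p = 0.583 with an estimated correlation) and 3.54e-05 for DNA replication (adjusted p = 0.349 with an estimated correlation).

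At 36 h, genes linked to the secondary wall of xylem cells were higher than at 0 h. All 3 measured secondary wall synthesis genes rose: IRX15 from a signal of 6.1 to 436 (log2 change 6.17 ± 0.82, adjusted p = 4.93e-05), IRX15-L by 7.37-fold and GUT2, a xylan glycosyltransferase gene, by 2.34 on the log2 scale (named after its value was seen). In a longer list of xylem wall associated genes, 18 of 20 rose and none fell, with a median of 2.78. That list was recalled from published co-expression with secondary wall genes after the annotation table was seen, and studies of induced xylem cells may have shaped it. It holds these 3 genes as well as AT1G66810 and scpl48, given next, so it is not independent of any of them. AT1G66810, the 1 measured gene of 25 listed xylem regulators, rose 4.78-fold. Of the cell death genes, the serine carboxypeptidase gene scpl48 rose 11.1-fold, and GAMMA-VPE fell (-1.24 ± 0.42), a call lost without 0 h replicate 1 (-0.81), 36 h replicate 1 (-1.06) or 36 h replicate 2 (-1.16). The 5 procambium and cambium genes were all higher, with CLE44 at 6.27-fold and MOL1 at 4.2-fold. In the mitosis list 16 of 17 genes rose, with UBC20 at 30.1-fold. The tubulin genes TUB1 and TUB7 rose 18.9-fold and 10.0-fold, in a list of 7 with 5 rises and 1 fall that was not called (camera adjusted p = 0.138). All 10 photosynthesis genes fell (median -4.69), as did 32 of 33 photosynthesis genes of the plastid (camera adjusted p = 3.81e-11, adjusted p = 0.490 with an estimated correlation). The highest changes were those of GSTU25, AT4G12500, AT5G45700 (8.96 ± 0.59), AT4G12490, the defensin gene PDF2.1 and AT3G44960, and the lowest those of AT4G15700 (-9.71 ± 1.33), AT4G15690, AT4G27654, AT2G22880, AT1G70820 and AT1G62510. Adjusted over the list alone, 3 secondary wall, 5 procambium and cambium and 6 auxin response genes rose, and 1 auxin response gene and 10 photosynthesis genes fell, as over all probe sets. A total of 10025 probe sets changed, 5767 up and 4258 down, and 8477 by at least 2-fold. The list tests gave adjusted p = 1.40e-04 for xylem wall associated genes (adjusted p = 0.349 with an estimated correlation), 0.0385 for procambium and cambium (adjusted p = 0.263 with an estimated correlation), 1.66e-05 for mitosis (adjusted p = 0.508 with an estimated correlation), and 4.66e-08 and 0.0188 for photosynthesis and auxin response (both adjusted p = 0.243 with an estimated correlation). Leaving out 0 h replicate 3 ended the procambium and cambium call (adjusted p = 0.0770).

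At 48 h, the last sampling, the 3 secondary wall synthesis genes were again higher than at 0 h. IRX15 was 124-fold above 0 h (log2 change 6.95 ± 0.82, adjusted p = 2.08e-05) and IRX15-L 9.73-fold. Of 4 measured lignin genes, AT5G66390 rose 81.7-fold from a 0 h signal of 1.8 and PRX52 rose (4.02 ± 1.15, or 2.63 without 0 h replicate 2), while CCR2, named after its value was seen, fell (-2.68, adjusted p = 0.0288). That fall was not called without 0 h replicate 1 (-2.69), 0 h replicate 2 (-2.34) or 48 h replicate 2 (-2.30). Among the xylem wall associated genes 18 of 20 rose and 1 fell, TBL30 (named after its value was seen), with AT5G40020 at 33.3-fold. The fall of TBL30 (-1.75) was not called without 48 h replicate 1 (-1.03) or 0 h replicate 3 (-1.51). The carboxypeptidase gene scpl48, also a member of the xylem wall associated list, reached 14.4-fold (adjusted p = 7.51e-07). All 5 procambium and cambium genes rose, CLE44 by 8.87-fold and MOL1 by 4.56-fold. Of 8 auxin response genes, 6 rose and 1 fell, with IAA30 at 117-fold. All 10 photosynthesis genes fell, with a median of -4.85, and the Calvin cycle enzyme gene PRK stood at -6.21 ± 0.65. SWEET11 was 107-fold lower than at 0 h, and the phloem gene OPS 14.1-fold higher. The defensin gene PDF1.2 (-3.90 ± 1.04) fell, as did FMA, the 1 measured guard cell gene (-1.94 ± 0.46). Of 2 measured senescence genes, WRKY53 fell (-3.08 ± 0.47) and WRKY6 rose (1.35 ± 0.43), the latter a call lost without 0 h replicate 1 (1.21). Among 3 reference genes, PEX4 rose 1.53-fold (adjusted p = 0.0284), with the call lost without 48 h replicate 1 (log2 change 0.47) or 0 h replicate 3 (0.47), and the other 2 did not pass the test. The highest changes were those of GSTU25, PDF2.1 (9.51 ± 0.99), AT5G02140, AT5G45700, AT4G12500 and AT4G12580, and the lowest those of AT2G22880 (-10.91 ± 1.13), AT1G70820, AT2G22760, AT4G15690, AT1G64360 and the zinc finger gene STZ. Adjusted over the list alone, 3 secondary wall, 5 procambium and cambium and 6 auxin response genes rose, and 1 auxin response gene and 10 photosynthesis genes fell. In total 10165 probe sets changed, 5939 up and 4226 down, and 8542 by at least 2-fold. Camera gave adjusted p = 4.06e-05 for xylem wall associated genes (adjusted p = 0.349 with an estimated correlation), 0.0297 for procambium and cambium (adjusted p = 0.250 with an estimated correlation), and 4.66e-08 and 0.0164 for photosynthesis and auxin response (both adjusted p = 0.243 with an estimated correlation). The procambium and cambium call ended without 0 h replicate 3 (adjusted p = 0.0597).

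**Figure D3:**
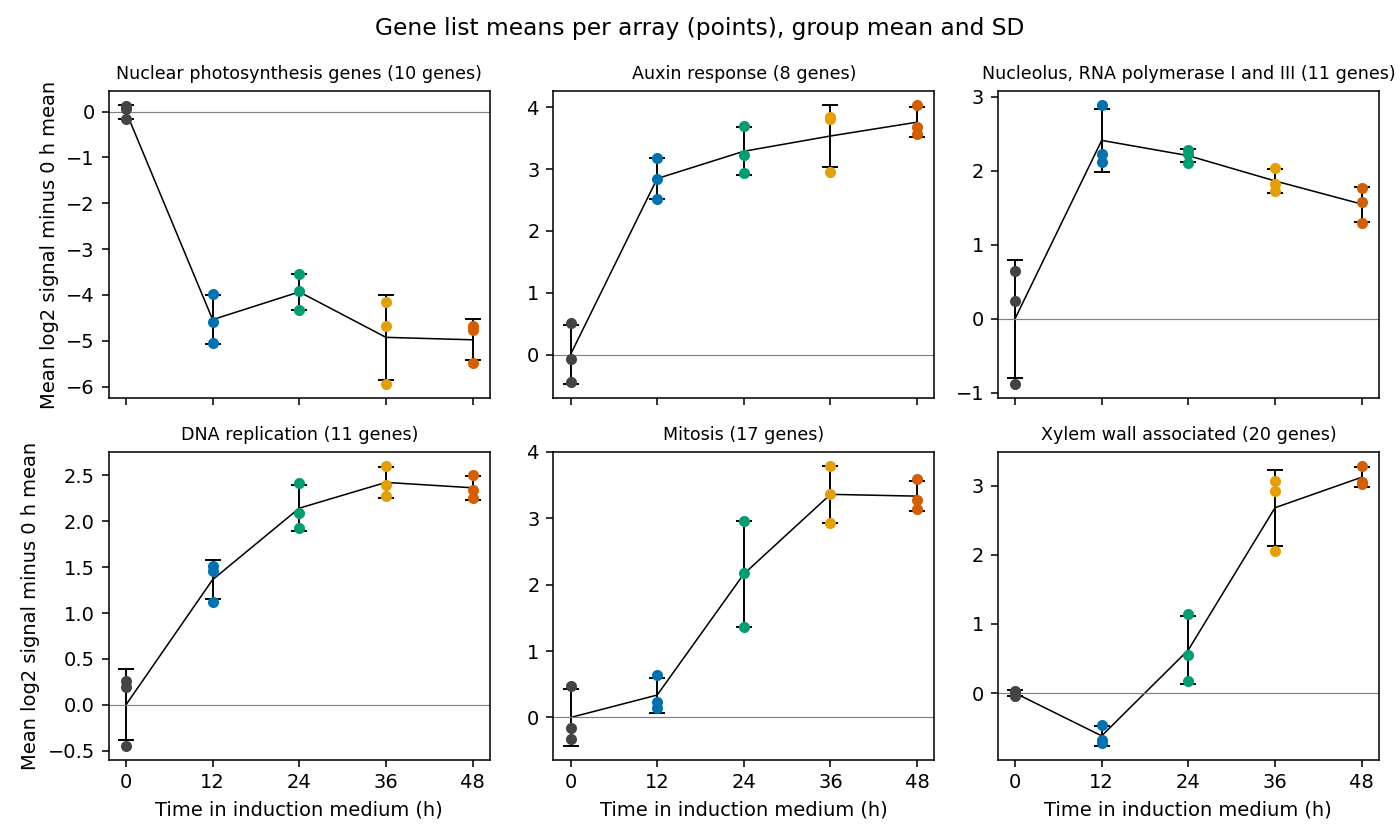
Mean log2 signal of 6 gene lists, minus the list's mean over the 0 h arrays, against time in induction medium in h. Points are single arrays, the line joins group means, and bars are the SD over 3 arrays. Photosynthesis genes lie below 0 from 12 h on, while xylem wall associated genes lie below 0 at 12 h and have their highest group mean at 48 h.

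Between 12 and 24 h, 6 of 17 genes of the mitosis list passed the test, all upward, and AUR2 rose 9.76-fold (log2 change 3.29 ± 0.64, adjusted p = 0.0312). The median of the list was 1.87. In the DNA replication list 2 of 11 rose, PRL by 3.27-fold and HTB2, named after its value was seen, by 1.43 on the log2 scale, and 9 were not called. The cell death gene scpl48 rose 2.82-fold and the beta-glucosidase gene BGLU15 14.8-fold. SWEET11 (-1.66 ± 0.28) and WRKY6 (-1.95 ± 0.43) fell. The highest changes were those of AT3G60650 (4.57 ± 0.98), AT1G49870, AT2G42110 and AT4G21820, and the lowest those of TRY, a regulator of trichome patterning (-4.05 ± 0.73), AT5G54720, UGT71B6 and AT1G31040. In all, 220 probe sets changed, 177 up (80.5%) and 43 down. With each array centred on its median, 98 of 146 rose (67.1%). Camera gave adjusted p = 9.22e-11 for mitosis (adjusted p = 0.349 with an estimated correlation). With the replicate number as a block, 440 of 711 probe sets called rose (61.9%), or 265 of 428 (61.9%) with the unnumbered 36 h array left out. No probe set changed without 12 h replicate 3, without 24 h replicate 1 or without 24 h replicate 2; 121 did without 12 h replicate 2 and 336 without 24 h replicate 3. AUR2 (2.99), PRL (1.72), scpl48 (1.32), BGLU15 (3.80), WRKY6 (-1.92), AT3G60650 (3.68), TRY (-4.17), AT5G54720 (-3.84) and UGT71B6 (-3.33) were not called without 12 h replicate 2, nor were AUR2 (3.34), scpl48 (1.38) and TRY (-3.85) without 12 h replicate 1, or AT3G60650 (4.63) without 24 h replicate 3. Array weights gave 3320 (57.2% up), the trend and robust setting 331, no filter 78 and the fit of only these 6 arrays 0.

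Between 24 and 36 h, the list of 20 xylem wall associated genes was higher (camera adjusted p = 1.23e-19, adjusted p = 0.0680 with an estimated correlation), with a median change of 2.12. Of its genes, 2 passed the test alone: AT5G51890 rose 7.94-fold (log2 change 2.99 ± 0.36, adjusted p = 0.013), from a signal of 718 to 5706, and AT2G41610 rose 6.05-fold. IRX15, IRX15-L and GUT2 had log2 changes of 3.94, 2.73 and 2.18 without passing the test over all probe sets; adjusted over the list alone, all 3 secondary wall synthesis genes rose. The 4 highest named changes were those of AT1G65810 (3.66 ± 0.43), AT5G51890, AT2G41610 and AT3G54040. The only other named genes called, AT2G22420 and AT4G24430, were picked out after their values were seen. The 10 photosynthesis genes had a median of -0.97 with none called (camera adjusted p = 2.77e-06, adjusted p = 0.243 with an estimated correlation); adjusted over the list alone, 2 fell. Their mean of -0.99 became -0.48 without 36 h replicate 3 (adjusted p = 0.0180), -0.59 with the replicate block and the unnumbered 36 h array left out, and -0.53 with array weights. In all, 20 probe sets changed and all rose; 14 of them are not named here. With quantile normalization 18 of 25 rose (72%). With the replicate number as a block, 55 of 68 probe sets called rose with the unnumbered 36 h array taken as number 3, and 71 of 84 with it left out. No probe set changed without 36 h replicate 1 or without 36 h replicate 2; 10 did without 24 h replicate 1, 37 without 24 h replicate 2, 8 without 24 h replicate 3 and 63 without 36 h replicate 3, with 9 of the 10 and 56 of the 63 upward. AT2G41610 (2.48 and 2.50), AT3G54040 (2.16 and 2.25), AT2G22420 (2.03 and 1.99) and AT4G24430 (1.75 and 1.77) were not called without 24 h replicate 1 or without 24 h replicate 3, nor was AT4G24430 without 24 h replicate 2 (1.84) or 36 h replicate 3 (1.61). Array weights gave 1946 (65.9% up), the offset 41 (92.7%), the stricter filter 43 (83.7%) and the fit of only these 6 arrays 0.

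Between 36 and 48 h, no probe set passed limma's test after adjustment, while 642 had an unadjusted p under 0.05. The count stayed at 0 with either form of the replicate block. Xylem wall associated genes had a median change of 0.42 (camera adjusted p = 0.0017, adjusted p = 0.490 with an estimated correlation). That call ended under the replicate block with the unnumbered 36 h array left out, where the mean log2 change was 0.13 (camera adjusted p = 0.512). It held under the block with that array as number 3. Relative to 0 h, the list's means at 36 h were 2.93, 3.07 and, on the unnumbered array, 2.05. At 48 h they were 3.29, 3.05 and 3.03, so the rise rests largely on the low value of that 1 array. Autophagy genes had a median change of 0.43 (adjusted p = 6.36e-06, adjusted p = 0.349 with an estimated correlation), with no member called. Photosynthesis genes of the plastid went down, with a median of -0.29 and none of 33 called (camera adjusted p = 2.50e-04, adjusted p = 0.594 with an estimated correlation). Their medians were -0.49 from 12 to 24 h and -0.51 from 24 to 36 h, also with none called.

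Over the whole course, 10703 probe sets (60%) differed between times by limma's F test. Of these, 3983 (37.2%) had their highest mean at 0 h, 1699 at 12 h, 1068 at 24 h, 1378 at 36 h and 2575 at 48 h. SWEET11 and the 10 photosynthesis genes were among those highest at 0 h, and IRX15, IRX15-L, GUT2 and scpl48 had their largest mean at 48 h. The time of the largest mean was not tested against the other times. Only 20 probe sets were called between 24 and 36 h and 0 between 36 and 48 h. The division among the later times is therefore descriptive.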

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

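The setting that leaves out all arrays of number 3 and the one that joins the stricter filter with the replicate block were chosen after seeing the data. Counts against 0 h stayed within 1.5 times under every setting run, with ranges of 7149 to 7712, 7558 to 8480, 8687 to 9543 and 9114 to 9812 at 12, 24, 36 and 48 h when 1 array was left out. The replicate block gave 9122, 9793, 10884 and 11038 with the unnumbered 36 h array as number 3. Not every pair with 0 h correlated above 0.1, though 14 of 14 numbered arrays correlated best with their own number.

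For 24 h against 12 h (220), the count was 146 with median centring, 78 with no filter, 331 with trend and robust estimation, 3320 with array weights, 0 with only the 2 times, 711 with the replicate block (428 with the unnumbered array left out), 1123 with the stricter filter and block, and 146 without number 3. Leaving out 1 array gave 0 to 336. For 36 h against 24 h (20), it was 41 with the offset, 43 with the stricter filter, 1946 with array weights, 0 with only the 2 times, 68 with the block (84 with the unnumbered array left out), 259 with the stricter filter and block, and 4 without number 3. Leaving out 1 array gave 0 to 63. For 48 h against 36 h the count was 0 in every setting run. Array weights gave the number 2 arrays of 12 to 48 h weights of 2.46 to 4.69 and all others at most 1.10; fits of only 2 times use fewer arrays. Other causes were not tested.

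With an estimated correlation all 71 called list tests lost their call. The setting leaves the mean log2 changes as they are, and those of the lists given most room were: auxin response 2.85, 3.29, 3.53 and 3.76 at 12, 24, 36 and 48 h against 0 h, photosynthesis -4.54, -3.93, -4.92 and -4.98 (36 h against 24 h -0.99, with -1.38 to -0.48 when 1 array was left out, the last without 36 h replicate 3, -0.53 with array weights and -0.59 with the replicate block and the unnumbered array left out), procambium and cambium 1.76 and 1.96 at 36 and 48 h, nucleolus 2.41 and DNA replication 1.36 at 12 h, mitosis 1.82 (24 h against 12 h), and xylem wall associated 2.06 (36 h against 24 h) and 3.12 (48 h against 0 h). The procambium and cambium call at 36 h was also lost with the stricter filter (1.76, adjusted p = 0.0762), the mean filter (1.76, 0.0568), the stricter filter and block (1.76, 0.0704) and without number 3 (1.55, 0.0971), and ranged from 1.61 to 2.03 when 1 array was left out. At 48 h it was lost with the stricter filter (1.96, 0.0613), the stricter filter and block (1.96, 0.0646) and without number 3 (1.71, 0.0815), and ranged from 1.81 to 2.24. The replicate block together with leaving out the unnumbered array ended 3 list calls, all between later times. With that array kept as number 3 the block ended none, so the block by itself did not end them. Leaving out that array without the block was not run for these 3 calls. The cause was not tested.

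AT1G66810 at 24 h against 0 h ranged from -0.28 to 0.83 and IRX15-L at 12 h from -0.98 to 0.11 when 1 array was left out; neither was called. The mean of nuclear photosynthesis genes from 12 to 24 h shrank from 0.446 to 0.064 with array weights and kept its sign, while the direction of the camera test turned (adjusted p = 0.886). Of 333 results of named genes, 59 changed side of the threshold in some setting other than leaving out 1 array. Signals below about 30.7 limit what folds of dim probe sets can show.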

Other observations

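Of 12 measured SWEET sugar transporter genes, 6 fell and none rose at 36 h against 0 h (camera adjusted p = 0.0141, adjusted p = 0.349 with an estimated correlation), with SWEET16 at -3.21 ± 0.74. Of 11 CYP71B genes, 8 fell at 48 h (adjusted p = 0.0043, adjusted p = 0.490 with an estimated correlation), with CYP71B22 at -5.41 ± 1.19. The cold-regulated genes COR15A and COR15B fell by 48 h (-7.05 ± 1.13 and -6.66 ± 0.46), but their list of 10, with 3 falls and 1 rise, was not called (adjusted p = 0.162). Among 10 autophagy genes 5 fell at 12 h, with ATG8E at -3.50 ± 0.47, and the list was not called (adjusted p = 0.286). The endoplasmic reticulum chaperone gene CRT1b rose 6.63-fold at 36 h, in a list of 13 with 6 rises and 2 falls that was not called (adjusted p = 0.198).

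The tests of scaling on the rises and on the xylem wall list, the test of culture stage, and the groupings drawn within replicate numbers were chosen after the result was seen. Other splits of the arrays were set beside the counts. In each comparison of 3 with 3 arrays, 10 splits cannot give a share under 0.05. Every other split also mixes both times on each side, so a difference between times widens the spread. The low counts of those splits therefore do not estimate false calls. The real counts, with the highest other split, were 8131 (4), 8843 (1), 10025 (1) and 10165 (1) against 0 h, 220 (0) from 12 to 24 h, 20 (1) from 24 to 36 h and 0 (4) from 36 to 48 h, so that 1 split of 10 reached the real count in the first 6 and 10 of 10 in the last. For the F test, 1 of 100 groupings of the 15 arrays, the real one, reached 10703, and the highest other gave 8073, which points to a structure of the samples. Those groupings ignore the replicate numbers. When 100 groupings kept 1 array of each number at each time, with the unnumbered 36 h array as number 3, again 1, the real one, reached 10703 and the highest other gave 5908. In both, 1 of 100 is the smallest share that 100 groupings can give, so chance is argued against but not excluded. The F test covers all times at once and does not tell which of them differ. From 12 to 24 h, the splits that part as many replicate pairs as the real one also gave at most 0.

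The first pattern is that more probe sets rose than fell at 48 h, 58.4% of those called. Centring each array on its median gave 50.2%, but centring itself brings rises and falls near balance, so that value decides nothing. With quantile normalization 55.3% rose, between the share with the authors' scaling and balance. Whether that scaling accounts for the excess of rises cannot be told apart from a real excess, because no measure of RNA content was used here.

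The second pattern is the higher level of xylem wall associated genes at 36 h than at 24 h, a mean log2 change of 2.06. Median centring gave a mean of 1.97. It moves a list only by the small shifts between the arrays' medians, so this value cannot decide on scaling. Scaling moves all probe sets of an array alike, and the median change of those kept from 24 to 36 h was 0.01. Scaling therefore leaves the rise of the list relative to the other probe sets as it is. A single array is argued against by a lowest mean of 1.83 with 1 array left out. As a hypothesis, the pattern may follow the time in the medium, which the design names. Its list was recalled from secondary wall co-expression, and cell numbers were not measured.

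The third pattern is that arrays of 1 number deviated together from 12 h on. The authors' scaling adds 1 constant to all log2 values of an array, which leaves a correlation across probe sets unchanged. It could therefore neither cause nor remove this pattern. After quantile normalization, which also evens out the distributions, the lowest same-number correlation among numbered arrays from 12 h on was 0.122. A candidate explanation is that samples of different numbers stood at different stages of 1 course. Deviations of number 1 correlated with the change over time at 0.302 at 24 h and 0.322 at 36 h, those of number 2 at 0.055 and -0.075, and those of number 3 at -0.362 and -0.164. The second largest size, 0.164, lies between the bounds set for and against it. A number at a stage between the other 2 could correlate near 0 with either sign, so those bounds could miss such a difference. On the second principal component the numbers lay in the order 1, 2, 3 at each later time. At 24 h the values were 4.6, -28.5 and -60.9, an order that other differences could also give. Stage therefore cannot be told apart from other differences between the numbered sets, technical ones included. The labels do not say that the numbers were separate cultures.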
